A study of Mus musculus with 19 samples.

How the data were processed

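RNA was measured in 19 libraries from mice 3 weeks old. NOD mice gave islet macrophages, lung macrophages and dendritic cells of the pancreatic lymph nodes, while NOD.Rag1-/- and B6.g7 animals gave islet macrophages. Per the labels, islets were dispersed for 5 min at 37 °C with a non-enzymatic solution, whereas lung and lymph nodes were digested with Liberase TL (125 ug/mL) and DNase I (50 ug/mL) for 30 min, so the dissociation differed with the tissue. Macrophages were sorted on CD45, F4/80 and I-Ag7 and dendritic cells on XCR1, with CD3e+ and CD19+ events gated out. The table names the dendritic cell columns after CD103 instead, and the labels were followed. Each sample held about 500 to 5000 cells pooled from 6 to 10 mice, and 1 to 50 ng of RNA was amplified with SeqPlex followed by 12 PCR cycles. The labels give no batches and no strandedness.

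The deposited table holds 46624 genes and 19 columns, all of them used, and its values are given here as normalized counts. Per the submitters' processing notes, STAR, HTSeq, DESeq2 1.6.3 and the genome build GRCm38.p4 were used, with no role or order stated. The deposited unit is a signal that, from the values themselves, equals gene read counts divided by one size factor per library and rounded to 1 decimal. In 18 libraries all low values were whole multiples of one step (within 0.1 of a step), and dividing by that step returned whole reads. In NOD.Rag1-/- replicate 3 the step of 0.318 was small against the rounding and only 62.0% of low values were whole, so this library was left out of edgeR and DESeq2, while its total, its thinned gene count and its chi-square against its replicates use reads estimated the same way. Recovered totals ran from 6824718 to 26184635 reads per library. Genes were placed on GRCm38 with GENCODE vM21: 42119 symbols matched directly and 839 by an older name, and 42855 (91.9%) had one position. Reads are assigned to whole genes, so near-identical genes (Ins1 and Ins2, the globins, H2 genes, Bcl2a1 genes) may share or lose reads, and Mir5107 lies within Cd74, beside Tcof1.

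The design written before the data were examined named edgeR on read counts, with limma on log2 values as the fallback for a table of normalized values. The table turned out to be normalized, so the fallback is the main test. limma 3.58.1 was run in R 4.3.3 with a mean-variance trend and a robust prior on log2(normalized count + 1), over genes with a mean of at least 1 in some group. The pseudocount of 1 makes the fold changes of genes with low counts smaller than their ratio of means. The 13 NOD libraries shared one fit for the cell-type comparisons and the 10 islet libraries another for strain and genotype. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a comparison, and genes with an adjusted p below 0.05 are called changed. No replicate block was used.

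Lists of genes were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over 32 lists and 4 comparisons. The lists cover macrophage and dendritic cell identity, inflammation and sensing, the regions around the targeted gene and the H2 complex, and markers of other cells. They were fixed, 33 in all, before the data were examined, and the one of sex-linked genes was not tested. camera with an estimated correlation and limma's fry were run beside it. camera compares a list with the other tested genes, whereas fry tests its members by themselves. For each list the called members were counted after adjustment over all genes and over the list alone. In list medians, a member whose libraries were all at 0 in a group was also set to the bound that 3 reads per library give.

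Named genes follow a rule set before the data were examined. For each comparison it takes the 8 highest and the 8 lowest log2 fold changes among called genes with a mean of at least 10 in the higher group, no overlap between libraries, and a symbol that is not a predicted gene or pseudogene. It adds up to 4 members with the smallest adjusted p from each list with a called member. It always includes the targeted gene Rag1, the sort genes Ptprc, Adgre1, Xcr1, H2-Aa, H2-Ab1, Cd3e and Cd19, and Il1b, Tnf, Tlr4 and Cd14 for the question on inflammation and sensing. Any other gene is marked as chosen after its values were seen.

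Alternatives chosen before the data were examined were no filter, a stricter filter, median-of-ratios rescaling, endocrine, exocrine and mitochondrial genes left out, pseudocounts of 0.5 and 10, a replicate block, each library left out in turn, no robust prior, all 19 libraries in one fit, only the groups compared, an added 2-fold threshold, sample quality weights, the estimated correlation, fry, and DESeq2 1.42.0. Chosen after seeing the data were edgeR 4.0.16 on recovered reads (DESeq2 ran on them too), quantile normalization, scaling to the total without rRNA, and leaving out the 2 cell-type libraries with the fewest genes (lung replicate 2 and dendritic cell replicate 3). Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes detected were compared after thinning each library to 5153097 reads without rRNA.

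The test was tested on simulated data with the real depths and 50 planted genes per fold size, drawn from genes with a mean of at least 10. Each gene had a single mean and a single spread for all groups, taken from the real data. Differences in spread between groups, such as the wider one of B6.g7, were not simulated, and the rates need not hold there. It recovered 6% to 16% of 2-fold, 34% to 42% of 4-fold, 52% to 68% of 8-fold and 70% to 76% of 16-fold changes over the 4 comparisons, with 4.60% to 9.38% false calls. Of 20 random lists, 2, 1, 0 and 0 fell below an unadjusted p of 0.05. Many real changes of moderate size would therefore be missed at these group sizes, and the false call rate can exceed the nominal one.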

Results

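Gene expression was measured by RNA sequencing in 19 libraries of sorted mouse cells. NOD mice, which develop autoimmune diabetes, gave 4 libraries of islet macrophages, 4 of lung macrophages and 5 of dendritic cells from the pancreatic lymph nodes, sorted on XCR1 per the labels but named after CD103 in the table. NOD.Rag1-/- mice, which lack T and B cells, gave 3 libraries of islet macrophages. B6.g7 mice, a C57BL/6 congenic strain that carries the H2 region of NOD, gave 3 more. The series title asks about the inflammatory state of islet macrophages and their sensing of microbial products. Values below are normalized counts, given as mean ± SD over these numbers of libraries (n = 4 NOD islet, 4 lung, 5 dendritic cell, 3 NOD.Rag1-/- and 3 B6.g7), and log2 fold changes carry their SE. Adjusted p-values come from limma unless another tool is named. Recovered totals were 9259148 to 14463487 reads in NOD islet libraries, 6824718 to 26184635 in NOD.Rag1-/- and 7061058 to 13379441 in B6.g7. They were 10037941 to 12116058 in lung and 8895194 to 11409521 in dendritic cell libraries. A gene listed at 0 gave no read in that library, which at these totals still allows an expected count of up to 3. Such limits cover counting error only, since amplified reads are not independent molecules.

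The libraries differed in quality in step with the groups. The 18S rRNA gene Rn18s-rs5 took 3.59% ± 0.70 of reads in NOD islet, 5.78% ± 0.42 in NOD.Rag1-/-, 12.1% ± 3.88 in B6.g7, 17.5% ± 7.56 in lung and 33.8% ± 4.55 in dendritic cell libraries. At equal depth 19356 to 26314 genes were detected in NOD islet libraries, 18115 to 22809 in NOD.Rag1-/-, 14758 to 17963 in B6.g7, 13028 to 17696 in lung and 13554 to 19629 in dendritic cells. Among 7625 genes with a mean of at least 100, B6.g7 libraries listed 84 to 112 at 0 and NOD islet libraries 5 to 20. Correlation across these genes within a group was likewise lower in B6.g7 (median r per library 0.763 to 0.798) than in NOD islet (0.947 to 0.959). Every pair of replicates differed by more than counting error (lowest chi-square per degree of freedom 20.2, with reads of NOD.Rag1-/- library 3 estimated only). This held in every group and covers counting error alone, so it does not rank the libraries by quality. Scaling to the total without rRNA moved the median log2 fold change of all tested genes from 0.41 to 0.70 for islet against lung. It moved from 0.38 to 0.62 against dendritic cells and from 0.42 to 0.63 for NOD against B6.g7. The direction of small differences thus depends on the scale. Among genes with a mean of at least 100 the medians in the main test were 0.05, −0.07 and −0.02. A list that camera calls lower lies below the other tested genes and need not lie below 0.

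**Figure D1:**
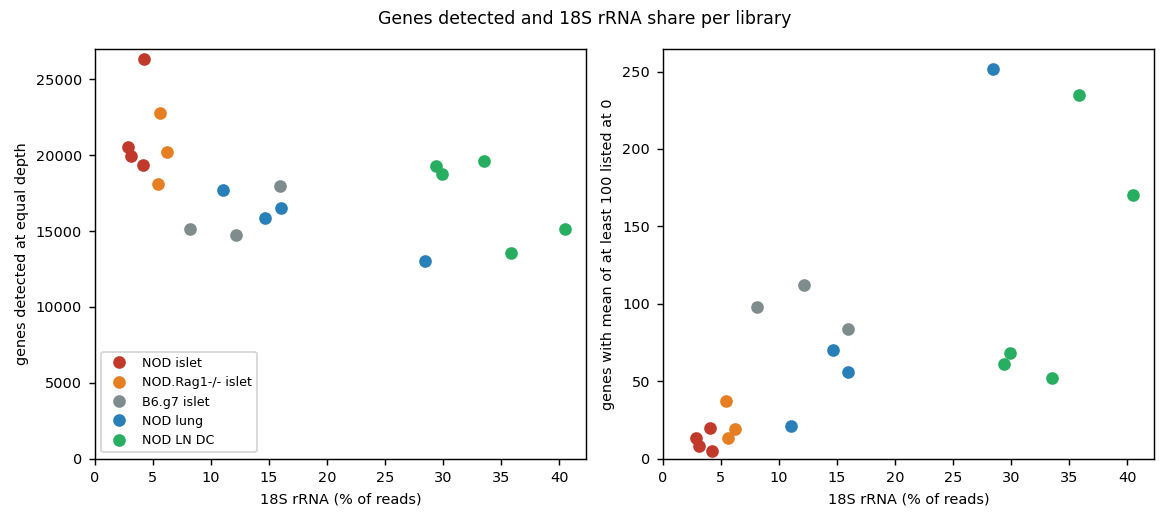
Genes detected at equal depth (left) and genes with a mean of at least 100 that are listed at 0 (right) against the percent of reads on 18S rRNA, with one point per library and colours for the 5 groups. NOD islet libraries lie at 2.87% to 4.26% 18S and B6.g7 libraries at 8.16% to 15.9%, with no overlap in either count.

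The first comparison set islet macrophages against lung macrophages of NOD mice, to see what is particular to macrophages resident in islets. Islet macrophages held far more Apoe, a lipid carrier (23314 ± 5912 against 932 ± 383, log2 fold change 4.71 ± 0.36, adjusted p = 6.3e-09). They also held more of the lysosomal protease Ctsb (18840 ± 761 against 5028 ± 531) and the lysosomal membrane gene Cd63 (1449 ± 260 against 148 ± 56.2). Tlr12, a Toll-like receptor gene, stood at 791 ± 279 against 3.6 ± 1.04 (log2 fold change 7.40 ± 0.54, adjusted p = 2.5e-09). Lung macrophages held more of the resistin-like gene Retnla (50.3 ± 46.3 in islet against 27302 ± 5657, log2 fold change −9.43 ± 0.69, adjusted p = 2.8e-09). The adhesion gene Flrt3 (17.4 ± 5.69 against 11100 ± 3096) and Tpbg (2.58 ± 3.29 against 1256 ± 165) were higher in lung as well. Csf2rb, a receptor chain for GM-CSF, was also lower in islet macrophages (2152 ± 233 against 19880 ± 2375, log2 fold change −3.21 ± 0.12, adjusted p = 5.7e-14), as was the transcription factor gene Bhlhe40. Of 26907 tested genes 3167 differed, 1639 higher and 1528 lower in islet macrophages, and 2807 of them by at least 2-fold. The libraries of the groups did not overlap in 20.7% of genes, against 2.86% by chance. The balance of directions depends on scale: 3291 were higher and 1049 lower when scaled to the total without rRNA, and 1213 higher and 1613 lower by edgeR on recovered reads. Tissue and dissociation cannot be separated here, since lung was digested with enzymes and islets were not.

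NF-kB targets were lower in islet than in lung macrophages, while cytokine and immediate-early genes went both ways. Il1b, the gene of interleukin 1 beta, stood at 7189 ± 2286 against 30804 ± 5167 (log2 fold change −2.14 ± 0.19, adjusted p = 5.6e-08). The prostaglandin synthase gene Ptgs2 stood at 1049 ± 77.4 against 4498 ± 439. The NF-kB subunit gene Rel stood at 6340 ± 1517 against 43962 ± 6216 (log2 fold change −2.81 ± 0.14, adjusted p = 1e-11), and Nfkb1 and Traf1 differed in the same direction. Nr4a3, an immediate-early transcription factor (chromosome 4, 48045153 to 48086447, GRCm38), had the smallest adjusted p of the genes named here (1054 ± 173 against 35918 ± 6148, log2 fold change −5.09 ± 0.12, adjusted p = 9.3e-17). In the opposite direction, islet macrophages held more of the chemokine gene Cxcl9 (2451 ± 1632 against 224 ± 34.6, log2 fold change 3.25 ± 0.30, adjusted p = 7.2e-08), a call lost with all 19 libraries in one fit. The immediate-early gene Egr1 was higher too (42727 ± 10908 against 6324 ± 660). Tnf was also higher (3640 ± 1253 against 1541 ± 764, log2 fold change 1.30 ± 0.30, adjusted p = 0.0056). This call was lost with sample quality weights and without the 2 libraries with the fewest genes. As a list, NF-kB targets were lower (17 lower and 1 higher of 26 over all genes, 19 and 1 adjusted over the list alone, median −1.36, adjusted p = 4.7e-19, and 0.015 with an estimated correlation). Inflammatory cytokines and chemokines were split, with 9 lower and 4 higher of 30 (10 and 7 adjusted over the list alone, median −0.19, adjusted p = 0.013). The list call was lost under quantile normalization (adjusted p = 0.19) and had adjusted p = 0.28 with an estimated correlation. Immediate-early genes had 10 lower and 7 higher of 27 (11 and 7 adjusted over the list alone, median −0.26, adjusted p = 0.0010, and adjusted p = 0.23 with an estimated correlation). That list was not called under quantile normalization or when scaled to the total without rRNA.

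Interferon-stimulated genes were higher in islet macrophages. Irf9, part of the interferon-activated transcription complex, stood at 689 ± 141 against 184 ± 83.1 (log2 fold change 1.99 ± 0.32, adjusted p = 0.00018). Oasl2 stood at 778 ± 228 against 153 ± 141. Of 35 list members 16 were higher and 0 lower (18 and 1 adjusted over the list alone, adjusted p = 4.2e-05). The median was 1.42, or 1.35 with members at 0 set to their bound, and the list had adjusted p = 0.17 with an estimated correlation. For microbial sensing, Tlr13 (1841 ± 351 against 341 ± 71.0) and Tlr1 (1047 ± 173 against 227 ± 87.4) were higher. Nod2, a sensor of bacterial cell walls, was lower (139 ± 21.5 against 1585 ± 350, log2 fold change −3.49 ± 0.29, adjusted p = 1.8e-08). The whole list of 42 sensing genes showed no shift (8 higher and 6 lower, 9 and 6 adjusted over the list alone, median −0.03, mean 0.34, adjusted p = 0.73). Tlr4, which senses lipopolysaccharide, was higher (301 ± 46.4 against 51.3 ± 42.6, adjusted p = 0.046) and its co-receptor gene Cd14 lower (2640 ± 663 against 15091 ± 1682, adjusted p = 0.044). Both calls lie near the threshold, in a fit whose spread includes dendritic cells, where both genes were low. Tlr4 was lost without any 1 of the NOD islet libraries or of lung libraries 2 to 4. Cd14 was lost without NOD islet libraries 1, 3 or 4 or lung libraries 1 to 3.

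Genes of antigen presentation and of dendritic cells were lower in islet than in lung macrophages. Cd80, a costimulatory ligand, stood at 100.1 ± 33.4 against 2957 ± 544 (log2 fold change −4.93 ± 0.28, adjusted p = 6e-11). The class II chaperone gene H2-DMb2 stood at 315 ± 40.05 against 3271 ± 600.1. The class II genes H2-Ab1 (26170 ± 10509 against 82069 ± 10076, adjusted p = 0.0038) and H2-Aa (43839 ± 18991 against 125182 ± 11703, adjusted p = 0.012) were also lower. The call for H2-Aa was lost with quality weights and under quantile normalization. The class II list had 11 lower and 3 higher of 18 (11 and 5 adjusted over the list alone, median −1.16, adjusted p = 1.7e-06). It was not called under quantile normalization (adjusted p = 0.066) and had adjusted p = 0.16 with an estimated correlation. Fscn1, an actin-bundling gene of mature dendritic cells (chromosome 5, 142960343 to 142973185), stood at 122 ± 27.1 against 3442 ± 464 (log2 fold change −4.83 ± 0.19, adjusted p = 1.5e-13). The mature dendritic cell list was lower with 17 lower and 1 higher of 22 (18 and 1 adjusted over the list alone, median −2.69, adjusted p = 1.5e-26, and 0.0069 with an estimated correlation). Zbtb46, a transcription factor of conventional dendritic cells, stood at 59.2 ± 23.7 against 1651 ± 568 (adjusted p = 4.2e-10). The growth factor receptor gene Kit stood at 52.3 ± 16.6 against 714 ± 162. The lectin gene Mgl2 (533 ± 206 against 23893 ± 5157) and Irf4 (134 ± 28.0 against 4398 ± 515), both common in type 2 conventional dendritic cells, were lower too.

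The macrophage core list was higher in islet macrophages (10 higher and 1 lower of 25, 16 and 3 adjusted over the list alone, median 1.61, adjusted p = 3.3e-05, and adjusted p = 0.063 with an estimated correlation). Genes of alveolar macrophages were lower (9 lower and 1 higher of 27, 10 and 3 adjusted over the list alone, median −1.19, adjusted p = 1.7e-06, and 0.0069 with an estimated correlation). Cell cycle genes were higher (8 higher and 0 lower of 30, 11 and 1 adjusted over the list alone, median 1.31, adjusted p = 0.0084). That list had adjusted p = 0.34 with an estimated correlation and was not called without NOD islet library 4 (adjusted p = 0.11). Heat shock genes were higher by the list test (median 0.79, adjusted p = 0.023, and adjusted p = 0.23 with an estimated correlation), a call lost without NOD islet library 1 (adjusted p = 0.070). Growth factors were lower (median −0.70, adjusted p = 0.028, and adjusted p = 0.29 with an estimated correlation), but not under quantile normalization or by edgeR (adjusted p = 0.12 in each) or without NOD islet library 2 (0.060) or lung library 1 (0.12). Matrix proteases and the H2 region were called lower (adjusted p = 0.018 and 0.017). These lists had adjusted p = 0.24 and 0.39 with an estimated correlation. Their medians were 0.23 and 0.06 and their means −0.60 and −0.02, so the sign depends on the measure. The median of all tested genes was 0.41, and camera called these lists lower than the other tested genes. The call for matrix proteases was lost under quantile normalization (adjusted p = 0.24), with a pseudocount of 10 and with all 19 libraries in one fit. The call for the H2 region was lost under quantile normalization (adjusted p = 0.96), scaled to the total without rRNA (0.51), by edgeR (0.12), by fry (0.20), with quality weights and with a stricter filter. With members at 0 set to their bound these medians were −0.02 and 0.03. Sort genes behaved unevenly: Ptprc, which encodes CD45, did not differ (9516 ± 1789 against 7741 ± 781, adjusted p = 0.15). Adgre1, which encodes F4/80, was 3963 ± 393 against 1145 ± 331 but not called (adjusted p = 0.13), although it was called by edgeR and DESeq2. Xcr1 was low in both (64.6 ± 95.9 against 14.2 ± 28.4, adjusted p = 0.043), and its call was lost without library 1, 2 or 3 of either.

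Markers of other cells moved with the tissue of origin. The hormone genes Gcg (1906 ± 1388 against 6.4 ± 8.15, log2 fold change 8.49 ± 1.18, adjusted p = 2.9e-05), Ins2 (4349 ± 3071 against 17.6 ± 15.4) and Sst (1176 ± 771 against 2.62 ± 2.36) were higher in islet macrophage libraries. Ppy was listed at 434 ± 326 against 0 in all lung libraries. Reads on insulin genes made up 0.101% ± 0.074 of reads without rRNA in NOD islet libraries and 0.00027% in lung. The endocrine list had 22 higher and 0 lower of 28 (25 and 0 adjusted over the list alone, adjusted p = 1.4e-16). Its median was 4.68, or 3.80 at the bound, and it had adjusted p = 0.055 with an estimated correlation. Rgs5, typical of pericytes, was higher (561 ± 323 against 13.02 ± 24.5, adjusted p = 0.00076). Siglech, common to plasmacytoid dendritic cells and some macrophages, stood at 1073 ± 253 against 20.3 ± 13.5 (adjusted p = 8.8e-06). Lung libraries carried surfactant Sftpc (listed at 0 against 1500 ± 698, adjusted p = 2.3e-08) and the chemokine Cxcl15 of airway epithelium (listed at 0 against 369 ± 181). They also carried globin Hba-a1 (10.8 ± 19.95 against 1133 ± 504, adjusted p = 5.7e-05). The globin Hbb-bs was higher in lung (174 ± 346 against 5482 ± 3326, adjusted p = 0.012), but not without NOD islet library 1, 3 or 4. Lung epithelium genes were lower in islet libraries (median −2.63, or −2.60 at the bound, adjusted p = 2.9e-07, and adjusted p = 0.11 with an estimated correlation). So were erythroid genes (median −1.45, or −1.02 at the bound, adjusted p = 0.00053, and adjusted p = 0.13 with an estimated correlation), which DESeq2 did not call (adjusted p = 0.076). Monocyte genes had a median of −1.01 (adjusted p = 0.00011, and adjusted p = 0.082 with an estimated correlation). Genes of type 2 dendritic cells had a median of −0.96 (adjusted p = 0.00080, and adjusted p = 0.13 with an estimated correlation). Those of type 1 dendritic cells were lower as well (median −0.56, adjusted p = 0.0019, and adjusted p = 0.33 with an estimated correlation). T cell genes had a median of −1.11 (adjusted p = 0.00031, and adjusted p = 0.32 with an estimated correlation). B cell genes were lower (median −1.21, or −0.70 at the bound, adjusted p = 0.0073, and adjusted p = 0.50 with an estimated correlation), but not by edgeR (adjusted p = 0.067), by fry, with a stricter filter or without lung library 4. Cd3e stood at 4.83 ± 4.56 against 96.6 ± 61.9 (adjusted p = 0.0065) and Cd19 at 1.75 ± 3.17 against 45.0 ± 22.3 (adjusted p = 0.016, lost without NOD islet library 1 or 3). Cells bearing either protein had been gated out. In all 21 of 32 lists were called, 5 higher and 16 lower, and 3 were called with an estimated correlation. By fry 17 of these 21 were called, without growth factors (adjusted p = 0.097), T cells (0.15), the H2 region (0.20) and B cells (0.28). The lists not called had adjusted p from 0.071 (exocrine cells) to 0.97 (mast cells, basophils and eosinophils).

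The second comparison set NOD islet macrophages against dendritic cells of the pancreatic lymph nodes, a professional antigen-presenting population of the same strain. Mmp12, a macrophage elastase, stood at 11950 ± 2572 against 1.0 ± 1.02 (log2 fold change 12.69 ± 0.35, adjusted p = 3.6e-16). The Fc receptor gene Fcgr1 stood at 4110 ± 984 against 0.24 ± 0.54 and the transcription factor Mafb at 6950 ± 596 against 3.02 ± 3.21 (log2 fold change 11.26 ± 0.53, adjusted p = 1.4e-12). The complement gene C1qc (9133 ± 482 against 5.7 ± 5.70) and the endocytic adaptor Dab2 (10352 ± 1542 against 6.18 ± 10.4) were likewise higher in macrophages. Dendritic cells held more Ccr7, the homing receptor to lymph nodes (51.8 ± 57.8 in macrophages against 13640 ± 3045, log2 fold change −8.59 ± 0.52, adjusted p = 4.5e-08). They also held more Wdfy4, needed for cross-presentation (1151 ± 137 against 30350 ± 8505, log2 fold change −4.69 ± 0.16, adjusted p = 1.4e-14), and Flt3, a growth factor receptor (62.5 ± 19.9 against 3732 ± 316). Fscn1 differed at 122 ± 27.1 against 32807 ± 7940 (log2 fold change −8.06 ± 0.18, adjusted p = 1.4e-17). Genes less known in this setting were also far higher in dendritic cells, such as Synpo2 (3.73 ± 2.28 against 7458 ± 1248, adjusted p = 5.7e-08) and Cacnb3 (15.3 ± 17.7 against 9706 ± 1090). Xcr1, on which the cells were sorted, stood at 64.6 ± 95.9 against 9955 ± 1639 (adjusted p = 8.7e-06) and Adgre1 at 3963 ± 393 against 15.7 ± 22.1 (adjusted p = 7.4e-09). Of the tested genes 4570 differed, 2447 higher and 2123 lower in macrophages, and 4117 by at least 2-fold. The libraries did not overlap in 22.6% of genes, against 1.59% by chance. Scaled to the total without rRNA, 3732 were higher and 1592 lower. Dissociation goes with the cell type here too, since lymph nodes were digested with enzymes and islets were not.

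The macrophage core list was higher (24 higher and 0 lower of 25, 24 and 1 adjusted over the list alone, median 7.33, adjusted p = 2.5e-37, and 0.00021 with an estimated correlation). The type 1 dendritic cell list was lower (25 lower and 0 higher of 26, median −5.09, adjusted p = 1.2e-39, and 0.0069 with an estimated correlation). So was that of mature dendritic cells (18 lower and 0 higher of 22, median −4.11, adjusted p = 1.1e-27, and 0.0069 with an estimated correlation). Macrophages held more of several cytokine genes: Il1a (6534 ± 2921 against 13.4 ± 14.2, adjusted p = 3.5e-08), Cxcl2 (11618 ± 3575 against 87.3 ± 44.3, log2 fold change 7.21 ± 0.38, adjusted p = 2.6e-10) and Il1b (7189 ± 2286 against 1526 ± 282, log2 fold change 2.20 ± 0.18, adjusted p = 9.2e-09). The T cell attractant Ccl5 was lower (292 ± 145 against 14021 ± 2457), and Tnf was not called (3640 ± 1253 against 2032 ± 537, adjusted p = 0.058). The cytokine list was higher (12 higher and 4 lower of 30, 16 and 5 adjusted over the list alone, median 2.18, or 1.47 at the bound, adjusted p = 0.00080, and adjusted p = 0.16 with an estimated correlation). NF-kB targets were lower (12 lower and 6 higher of 26, 14 and 6 adjusted over the list alone, median −0.58, adjusted p = 0.0032, and adjusted p = 0.32 with an estimated correlation). This list was not called by edgeR (adjusted p = 0.068), under quantile normalization (0.45) or scaled to the total without rRNA (0.13).

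Microbial sensing genes were higher in islet macrophages than in dendritic cells. Tlr2, which senses bacterial lipopeptides, stood at 3982 ± 1118 against 178 ± 51.2 (log2 fold change 4.50 ± 0.25, adjusted p = 1.4e-11). The beta-glucan receptor Clec7a stood at 2614 ± 314 against 324 ± 112 and the inflammasome gene Nlrp3 at 2998 ± 914 against 490.2 ± 142. Tlr4 was higher at 301 ± 46.4 against 10.8 ± 7.46 (adjusted p = 0.00012) and Cd14 at 2640 ± 663 against 34.8 ± 28.3 (adjusted p = 1.1e-05). Tlr3, which senses double-stranded RNA, was lower (394 ± 79.1 against 3901 ± 879.6, log2 fold change −3.30 ± 0.26, adjusted p = 3.6e-09). Of 42 list members 21 were higher and 5 lower (26 and 5 adjusted over the list alone, median 1.71, adjusted p = 1.5e-06, and adjusted p = 0.055 with an estimated correlation). Scavenger and phagocytic receptors were higher (17 higher and 3 lower of 25, median 4.87, adjusted p = 4e-10, and 0.011 with an estimated correlation). Among them the lipoprotein receptor Lrp1 stood at 6630 ± 2017 against 184 ± 80.2 and Stab1 at 2750 ± 373 against 8.62 ± 4.83. Matrix proteases were higher as well (15 higher and 1 lower of 24, 16 and 2 adjusted over the list alone, median 2.60, or 2.37 at the bound, adjusted p = 2.8e-09, and 0.015 with an estimated correlation). Adam8 of that list was lower (257 ± 94.5 against 12040 ± 1225). The H2 region was lower (21 lower and 3 higher of 37, 24 and 5 adjusted over the list alone, median −1.09, adjusted p = 8.9e-14, and 0.040 with an estimated correlation). Of its members, the peptide transporter Tap1 stood at 346 ± 52.9 against 5684 ± 733 and the class I gene H2-D1 at 4836 ± 1144 against 16091 ± 1757. Class II presentation genes were lower (10 lower and 5 higher of 18, median −0.74, adjusted p = 0.0014, and adjusted p = 0.30 with an estimated correlation), but not by DESeq2 (adjusted p = 0.13) or under quantile normalization (0.46). H2-Ab1 was lower (26170 ± 10509 against 64139 ± 4920, adjusted p = 0.0066) and H2-Aa was not called (43839 ± 18991 against 47136 ± 7655, adjusted p = 0.68). The protease Ctss of that list was higher (10388 ± 2608 against 517 ± 80.9, adjusted p = 1.2e-13).

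Lymphocyte genes were higher in the dendritic cell libraries, although CD3e+ and CD19+ events had been gated out. Cd3e stood at 4.83 ± 4.56 against 235 ± 141 (adjusted p = 0.00037) and Cd19 at 1.75 ± 3.17 against 187 ± 124 (adjusted p = 0.00065). The T cell factor gene Tcf7 stood at 7.58 ± 4.32 against 887 ± 253 and the antibody light chain gene Igkc at 21.5 ± 29.9 against 6934 ± 3865 (adjusted p = 0.00091). The T cell list was lower in macrophages (17 lower and 1 higher of 21, median −4.23, or −3.90 at the bound, adjusted p = 2.8e-09, and adjusted p = 0.16 with an estimated correlation). So were B cell genes (median −2.91, or −1.99 at the bound, adjusted p = 5.5e-08, and adjusted p = 0.21 with an estimated correlation). NK cell genes were lower too (median −0.99, or −0.96 at the bound, adjusted p = 0.0019, and adjusted p = 0.21 with an estimated correlation). Exocrine genes were lower in macrophages too (median −3.63, adjusted p = 1.6e-06, and adjusted p = 0.32 with an estimated correlation). The pancreatic protease gene Cpa1 stood at 5.97 ± 9.16 against 178 ± 187 (adjusted p = 0.0082). Endocrine genes were higher (median 4.42, or 4.20 at the bound, adjusted p = 6.4e-17, and adjusted p = 0.055 with an estimated correlation), and Ins2 was listed at 0 in all 5 dendritic cell libraries. Genes of fibroblasts and pericytes were higher in macrophages (median 2.49, or 2.40 at the bound, adjusted p = 0.0018, and adjusted p = 0.21 with an estimated correlation). Neutrophil genes were called higher (median 1.30, or 0.30 at the bound, adjusted p = 0.023, and adjusted p = 0.32 with an estimated correlation). That call was lost with a stricter filter, with a pseudocount of 10, by edgeR, scaled to the total without rRNA and without NOD islet library 1. Endothelial genes were higher too (median 2.60, adjusted p = 0.040, and adjusted p = 0.43 with an estimated correlation), as were growth factors (median 0.82, or 0.76 at the bound, adjusted p = 0.047, and adjusted p = 0.32 with an estimated correlation). The calls for endothelium and growth factors lie near the threshold. Both were lost by edgeR and without NOD islet libraries 1 or 3 or dendritic cell library 3. Endothelium was also lost with all 19 libraries in one fit and without the 2 libraries with the fewest genes, and growth factors with a stricter filter, with a pseudocount of 10 and without NOD islet library 4. In all 19 of 32 lists were called, 10 higher and 9 lower (7 and 8 by edgeR), and 6 were called with an estimated correlation. The others had adjusted p from 0.054 (cholesterol synthesis and efflux) to 0.70 (lung epithelium).

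Genes higher in islet macrophages than in both other populations numbered 697, and 745 were lower than in both. Scaled to the total without rRNA these counts were 1409 and 477. Independent lists of these sizes would share 149 and 121. With the NOD islet libraries split between the comparisons, so that no library served both, 242 to 266 genes were higher and 469 to 521 lower over 6 splits, where independent lists would share 26 to 30 of the higher ones. In 20 simulations with unchanged groups that shared their controls no gene was called in both, but such simulations hold no effects and give no value for long lists. Hormone genes head the shared list, and Apoe is on it, at 23314 ± 5912 against 932 ± 383 in lung and 104 ± 58.2 in dendritic cells. Lung and lymph nodes were both digested with enzymes, unlike islets. Fewer genes were detected there at equal depth (means 15782 and 17282 against 21531). The shared genes therefore cannot separate islet macrophages from dissociation, nor the higher ones from capture.

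**Figure D2:**
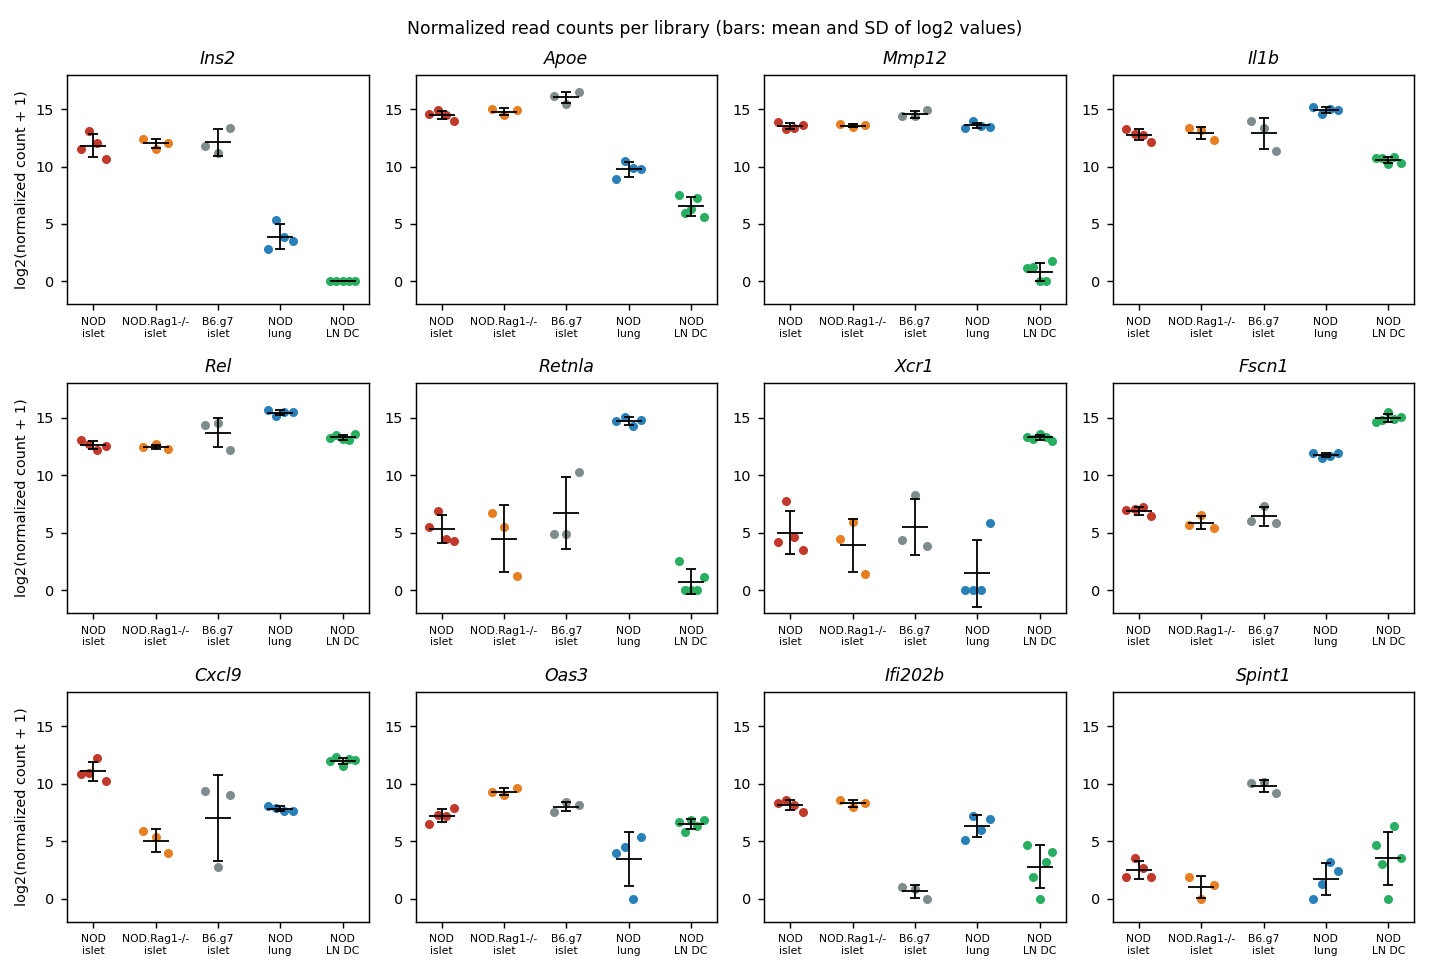
Normalized counts of 12 named genes as log2(normalized count + 1), with one point per library in the 5 groups and bars for the mean and SD of the log2 values. Ins2 is at 0 in all 5 dendritic cell libraries, Retnla is highest in lung macrophages (27302 ± 5657), and Ifi202b is at or below 1.0 in all B6.g7 libraries.

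The third comparison set NOD against B6.g7 islet macrophages, a diabetes-prone against a diabetes-resistant strain with the same class II type. Ifi202b, an interferon-inducible gene of the p200 family (chromosome 1, 173962568 to 173982744), stood at 293 ± 77.8 against 0.6 ± 0.53 (log2 fold change 7.54 ± 0.48, adjusted p = 5.2e-06), and reached 319 ± 66.9 in NOD.Rag1-/- libraries. The antisense gene BC018473 (1055 ± 951 against 4.27 ± 1.25) and Tpm3-rs7 (797 ± 112 against 12.4 ± 9.59) were also higher in NOD. Tlr5, which senses flagellin, stood at 53.0 ± 13.3 with all B6.g7 libraries listed at 0 (adjusted p = 0.00053). Lower in NOD were the protease inhibitor gene Spint1 (5.22 ± 3.56 against 930.5 ± 297, log2 fold change −7.33 ± 0.76, adjusted p = 0.00016) and Trim12a (0.45 ± 0.61 against 131 ± 74.3). The same held for Pydc4 (3.38 ± 2.49 against 215 ± 127) and the drug transporter gene Abcb1b (8.8 ± 7.60 against 325 ± 109). Reads were assigned to a reference built from C57BL/6, so a NOD sequence that differs from it can lose reads. Of 26506 tested genes 1320 differed, 871 higher and 449 lower in NOD, and 1172 by at least 2-fold. Among the 871 higher genes, 440 (50.5%) had 2 or 3 B6.g7 libraries at 0. Libraries did not overlap in 16.9% of genes, against 5.71% by chance. The excess of higher genes moved with the settings. Scaled to the total without rRNA, 1717 were higher and 229 lower, and a pseudocount of 10 gave 53.2% higher. On recovered reads edgeR, which tested 16827 genes, called 316 higher and 337 lower, whereas DESeq2 called 1459 higher and 1069 lower, both without NOD.Rag1-/- library 3 in the fit. The count itself was 814 with quality weights, 500 with all 19 libraries in one fit, 438 with only these groups in the fit, 856 with a pseudocount of 10 and 848 under quantile normalization. It was 441, 531, 397 and 716 without NOD islet libraries 1, 2, 3 and 4, and 2028 and 3156 without B6.g7 libraries 2 and 3.

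Among macrophage genes the strains differed in both directions. The Fc receptor subunit Fcer1g was lower in NOD (5160 ± 1186 against 17855 ± 1114, log2 fold change −1.82 ± 0.17, adjusted p = 7.4e-05). Fcgr1 was higher (4110 ± 984 against 1146 ± 242, log2 fold change 1.83 ± 0.22, adjusted p = 0.00053). Apoe was lower (23314 ± 5912 against 69202 ± 22080, log2 fold change −1.55 ± 0.23, adjusted p = 0.0024), as was C1qa (4482 ± 187 against 9058 ± 276). Both calls were lost with all 19 libraries in one fit. The scavenger receptor Cd36 stood at 938 ± 350.5 against 6105 ± 2714 (log2 fold change −2.65 ± 0.34, adjusted p = 0.00086). The inflammasome gene Nlrp1b stood at 129 ± 18.3 against 674 ± 61.1 (adjusted p = 0.00027, lost with all 19 libraries in one fit). The macrophage core list was lower (7 lower and 2 higher of 25, 9 and 2 adjusted over the list alone, median −0.28, adjusted p = 3.7e-05, and adjusted p = 0.24 with an estimated correlation). The direction of this list reversed under quantile normalization (adjusted p = 0.68) and it was not called without B6.g7 library 3 (adjusted p = 0.16).

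Immediate-early genes, NF-kB targets and cytokine genes were called lower as lists by camera in NOD than in B6.g7 islet macrophages. By fry only the first of these was called (adjusted p = 0.031, against 0.19 and 0.16). The chemokine gene Ccl3 stood at 2940 ± 464 against 12786 ± 3492 (log2 fold change −2.10 ± 0.19, adjusted p = 6.6e-05, lost with all 19 libraries in one fit). The AP-1 gene Junb stood at 3646 ± 986 against 11165 ± 2689 (log2 fold change −1.62 ± 0.21, adjusted p = 0.00099) and Zc3h12a, which degrades cytokine mRNA, at 727 ± 52.0 against 1998 ± 344 (adjusted p = 0.00063). Immediate-early genes were lower as a list (5 lower and 0 higher of 27, 16 and 1 adjusted over the list alone, median −0.79, adjusted p = 1.2e-12, and adjusted p = 0.13 with an estimated correlation). So were NF-kB targets (2 lower and 0 higher of 26, 7 and 0 adjusted over the list alone, median −0.42, adjusted p = 2.9e-07, and adjusted p = 0.28 with an estimated correlation). Inflammatory cytokines and chemokines were lower as well (4 lower and 1 higher of 30, 7 and 2 adjusted over the list alone, median −0.53, adjusted p = 1.5e-05, and adjusted p = 0.16 with an estimated correlation). The B6.g7 libraries were not alike in this. The median difference of NOD from B6.g7 libraries 1, 2 and 3 was −1.11, −0.95 and −0.24 for immediate-early genes, −0.64, −0.70 and 0.05 for NF-kB targets and −0.54, −1.01 and −0.32 for cytokines. Tnf was lower (3640 ± 1253 against 8957 ± 4103, adjusted p = 0.048), a call lost without any 1 NOD library or B6.g7 library 1 or 2. Il1b (7189 ± 2286 against 9612 ± 6717, adjusted p = 0.93), Tlr4 (301 ± 46.4 against 417 ± 191, adjusted p = 0.49) and Cd14 (2640 ± 663 against 3407 ± 666, adjusted p = 0.34) were not called. Microbial sensing genes showed no shift as a list (1 higher and 3 lower of 42, 6 and 3 adjusted over the list alone, adjusted p = 0.20), nor did interferon-stimulated genes (2 higher and 2 lower of 35, adjusted p = 0.13).

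The invariant chain gene Cd74 was lower in NOD (38397 ± 12112 against 135747 ± 28162, log2 fold change −1.87 ± 0.26, adjusted p = 0.0040, lost with quality weights and under quantile normalization). H2-Ab1 was not called (26170 ± 10509 against 64603 ± 14852, adjusted p = 0.055). Class II presentation genes were lower as a list (1 lower and 0 higher, 3 and 0 adjusted over the list alone, median −0.38, adjusted p = 0.00030, and adjusted p = 0.31 with an estimated correlation). The H2 region was lower too (3 lower and 0 higher of 37, 6 and 0 adjusted over the list alone, median −0.25, adjusted p = 0.00075, and adjusted p = 0.28 with an estimated correlation). Neither was called under quantile normalization (adjusted p = 0.77 and 0.36) or without B6.g7 library 1 (0.063 and 0.052). Scavenger receptors were lower (median −0.28, adjusted p = 0.00083, and adjusted p = 0.11 with an estimated correlation). So were matrix proteases (median −0.29, adjusted p = 0.0076, and adjusted p = 0.16 with an estimated correlation). Growth factors followed (median −0.21, adjusted p = 0.017, and adjusted p = 0.32 with an estimated correlation). None of these 3 lists was called under quantile normalization. Without B6.g7 library 3 the scavenger list had an adjusted p of 0.097 and the growth factor list 0.23. The growth factor call was also lost without B6.g7 library 2 (0.070), by edgeR, with quality weights and with a stricter filter. Endocrine genes were higher (7 higher and 0 lower, 11 and 0 adjusted over the list alone, median 2.31, or 2.05 at the bound, adjusted p = 8e-06, and adjusted p = 0.27 with an estimated correlation). The channel subunit Abcc8 stood at 59.6 ± 29.8 against 0.33 ± 0.58 (adjusted p = 0.0055). The share of reads on insulin genes, by contrast, was close in NOD (0.101% ± 0.074) and B6.g7 (0.091% ± 0.085). Monocyte genes were higher (median 1.85, or 1.75 at the bound, adjusted p = 0.029, and adjusted p = 0.21 with an estimated correlation), but not without NOD islet library 1 or 3 or any B6.g7 library, by edgeR, by DESeq2 or with a stricter filter. In all 11 of 32 lists were called by camera, 2 higher and 9 lower, and 0 with an estimated correlation. Under quantile normalization 5 were higher and 3 lower. By fry 4 were higher and 1 lower, and only 3 of these 5 were among the 11, namely immediate-early, endocrine and monocyte genes. The others had adjusted p from 0.10 (exocrine cells) to 0.94 (NK cells, and mast cells, basophils and eosinophils).

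NOD.Rag1-/- islet macrophages, taken as a further comparison with B6.g7, differed in 1421 genes, 895 higher and 526 lower. The balance turned in other settings, with 78 higher and 142 lower with only these groups in the fit and 219 higher and 229 lower by edgeR, which also lacked NOD.Rag1-/- library 3. The count was 595, 523 and 508 without NOD.Rag1-/- libraries 1, 2 and 3, and 2158, 2189 and 3208 without B6.g7 libraries 1, 2 and 3. Groups did not overlap in 20.2% of genes, against 10.0% by chance. Scaled to the total without rRNA, 1291 were higher and 400 lower. Spint1 stood at 1.33 against 930.5 (adjusted p = 8.2e-05). Of the genes called, 543 were higher and 235 lower in both NOD and NOD.Rag1-/- than in B6.g7, where independent lists would share 29 and 9. With only the compared groups in each fit, 47 were higher and 83 lower in both. The 20 simulations of unchanged groups gave 0 here as well, with the same limit. The 3 B6.g7 libraries serve both comparisons and are too few to split, so part of this overlap can come from the shared controls. Without B6.g7 libraries 1, 2 and 3 the overlap was 1256, 1348 and 2179 genes, and without any 1 NOD or NOD.Rag1-/- library it was 313 to 456.

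The fourth comparison set NOD.Rag1-/- against NOD islet macrophages, to ask what depends on lymphocytes. Rag1 itself (chromosome 2, 101638282 to 101649501) was listed at 6.7, 1.3 and 8.6 in the NOD.Rag1-/- libraries, at 0 in all 4 NOD islet libraries, and at 0, 95.8 and 2.9 in B6.g7. It was 20.9 in lung library 1 and 0 in the other lung libraries, and 1.2 and 1.7 in dendritic cell libraries 1 and 4 and 0 in the rest. Reads are counted over the whole gene and macrophages need not express it, so these values do not check the genotype (adjusted p = 0.83). Higher in NOD.Rag1-/- were the membrane protein gene Plxdc2 (chromosome 2, 16356304 to 16755839) at 7295 ± 491 against 3140 ± 623 (log2 fold change 1.23 ± 0.16, adjusted p = 0.032) and the adaptor gene Fyb (13115 ± 506 against 5999 ± 1074, log2 fold change 1.15 ± 0.16, adjusted p = 0.032). The mitochondrial carrier Ucp2 was higher too (36481 ± 7206 against 17128 ± 2273, adjusted p = 0.036). Rnf213 (7194 ± 896 against 4001 ± 283), Tcof1 (2320 ± 266 against 1149 ± 152) and Mir5107, which lies within Cd74 (1414 ± 127 against 461 ± 148), were higher too. Lower were the endoplasmic reticulum chaperone Hspa5 (9820 ± 802 against 24578 ± 5991, log2 fold change −1.29 ± 0.18, adjusted p = 0.032) and metallothionein Mt2 (287 ± 74.2 against 2021 ± 916, log2 fold change −2.66 ± 0.41, adjusted p = 0.043). Hprt (114 ± 32.5 against 500.2 ± 115) and tubulin Tuba1c (841 ± 154 against 2147 ± 426) were lower as well. The predicted genes Gm23935 (higher) and Gm13710 (lower), chosen after their values were seen, complete the 12 called genes, 7 higher and 5 lower. An unadjusted p below 0.05 was reached by 1679 genes. Groups did not overlap in 13.3% of genes, against 5.71% by chance. This count is not stable. It was 1000 with sample quality weights, 1022 with only these groups in the fit and 30 with all 19 libraries in one fit. It was 0, 1, 1 and 68 without NOD islet libraries 1, 2, 3 and 4, and 0 without any 1 of the NOD.Rag1-/- libraries. It was 0 by edgeR and 52 by DESeq2 (19 higher and 33 lower), both without NOD.Rag1-/- library 3.

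Inflammatory genes leaned lower and interferon-stimulated genes higher in NOD.Rag1-/- than in NOD islet macrophages, as lists rather than as single genes. No member of either list was called by limma over all genes, and the members named here were chosen after their values were seen. Oas3 stood at 642 ± 140 against 155 ± 60.9 (adjusted p = 0.057), Oas2 at 1094 ± 322 against 399 ± 61.7 (adjusted p = 0.074) and Oasl2 at 1926 ± 143 against 778 ± 228 (adjusted p = 0.090). Ptgs2 stood at 352 ± 126 against 1049 ± 77.4 (adjusted p = 0.074) and Cxcl9 at 36.6 ± 21.2 against 2451 ± 1632 (adjusted p = 0.28). With only these groups in the fit, 10 interferon-stimulated genes were higher, Oas3 having an adjusted p of 6.5e-05, and 1 was lower (Gbp2). On the cytokine list 1 gene was higher (Tgfb1) and 3 were lower (Ptgs2, Cxcl9 and Cxcl10). The interferon-stimulated list was higher (31 of 35 members higher, 5 called and 0 lower adjusted over the list alone, median 0.48, adjusted p = 3.8e-09, and adjusted p = 0.096 with an estimated correlation). Cytokines and chemokines were lower (5 of 30 members higher, 9 called lower and 1 higher adjusted over the list alone, median −0.95, adjusted p = 1e-08, and adjusted p = 0.092 with an estimated correlation). Il1b (8167 ± 2606 against 7189 ± 2286, adjusted p = 1.0), Tnf (2201 ± 638 against 3640 ± 1253, adjusted p = 0.80), Tlr4 (334 ± 30.2 against 301 ± 46.4, adjusted p = 0.98) and Cd14 (1480 ± 197 against 2640 ± 663, adjusted p = 0.23) were not called.

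Further lists differed between these genotypes. Heat shock genes were lower (median −0.45, adjusted p = 9.9e-05, and adjusted p = 0.11 with an estimated correlation). Hspa5 was the 1 called member over all genes, and 2 members were lower and 1 higher adjusted over the list alone. No member of the other lists called in this comparison was called over all genes. Mature dendritic cell genes were lower (median −0.83, adjusted p = 0.00018, and adjusted p = 0.15 with an estimated correlation). NF-kB targets were lower (median −0.27, adjusted p = 0.0051, and adjusted p = 0.50 with an estimated correlation), as were endocrine genes (median −0.87, adjusted p = 0.0010, and adjusted p = 0.37 with an estimated correlation). Monocyte genes were lower (median −0.71, adjusted p = 0.013, and adjusted p = 0.16 with an estimated correlation). So were alveolar macrophage genes (median −0.38, or −0.15 at the bound, adjusted p = 0.027, and adjusted p = 0.39 with an estimated correlation). Exocrine genes were higher (median 1.33, adjusted p = 0.00081, and adjusted p = 0.32 with an estimated correlation). So were genes of endothelium (median 1.09, adjusted p = 0.0034, and adjusted p = 0.50 with an estimated correlation) and of class II presentation (median 0.20, adjusted p = 0.047, and adjusted p = 0.52 with an estimated correlation). The list calls for NF-kB targets, endocrine genes and monocytes were lost without NOD.Rag1-/- library 3 (adjusted p = 0.090 in each). Without NOD islet library 1 NF-kB targets (0.16) and monocytes (0.078) were not called either, nor were monocytes without NOD islet library 3 (0.056) or by edgeR (0.11). The call for alveolar macrophages was lost without NOD.Rag1-/- library 3 (0.26), without NOD islet library 1 (0.078) or 4 (0.13) and by edgeR (0.15), and that for endothelium without NOD.Rag1-/- library 2 (0.14). Class II presentation was lost in most settings. Genes flanking Rag1 were not called as a list by camera (adjusted p = 0.58), nor in the other comparisons (0.52 against lung, 0.10 against dendritic cells, 0.43 for NOD against B6.g7). By fry they were called for NOD against B6.g7 (adjusted p = 0.00031), where their median of 0.37 lay below the median of all tested genes (0.42). Of 46 tested members 3 were higher and 2 lower there, and 3 were higher and 7 lower against dendritic cells. Microbial sensing showed no shift (adjusted p = 0.53). In all 11 of 32 lists were called by camera, 4 higher and 7 lower, and 0 with an estimated correlation. By fry 5 were called, of which only 3 were among the 11, namely cytokines, interferon-stimulated genes and heat shock. The others had adjusted p from 0.053 (T cells) to 0.94 (NK cells).

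**Figure D3:**
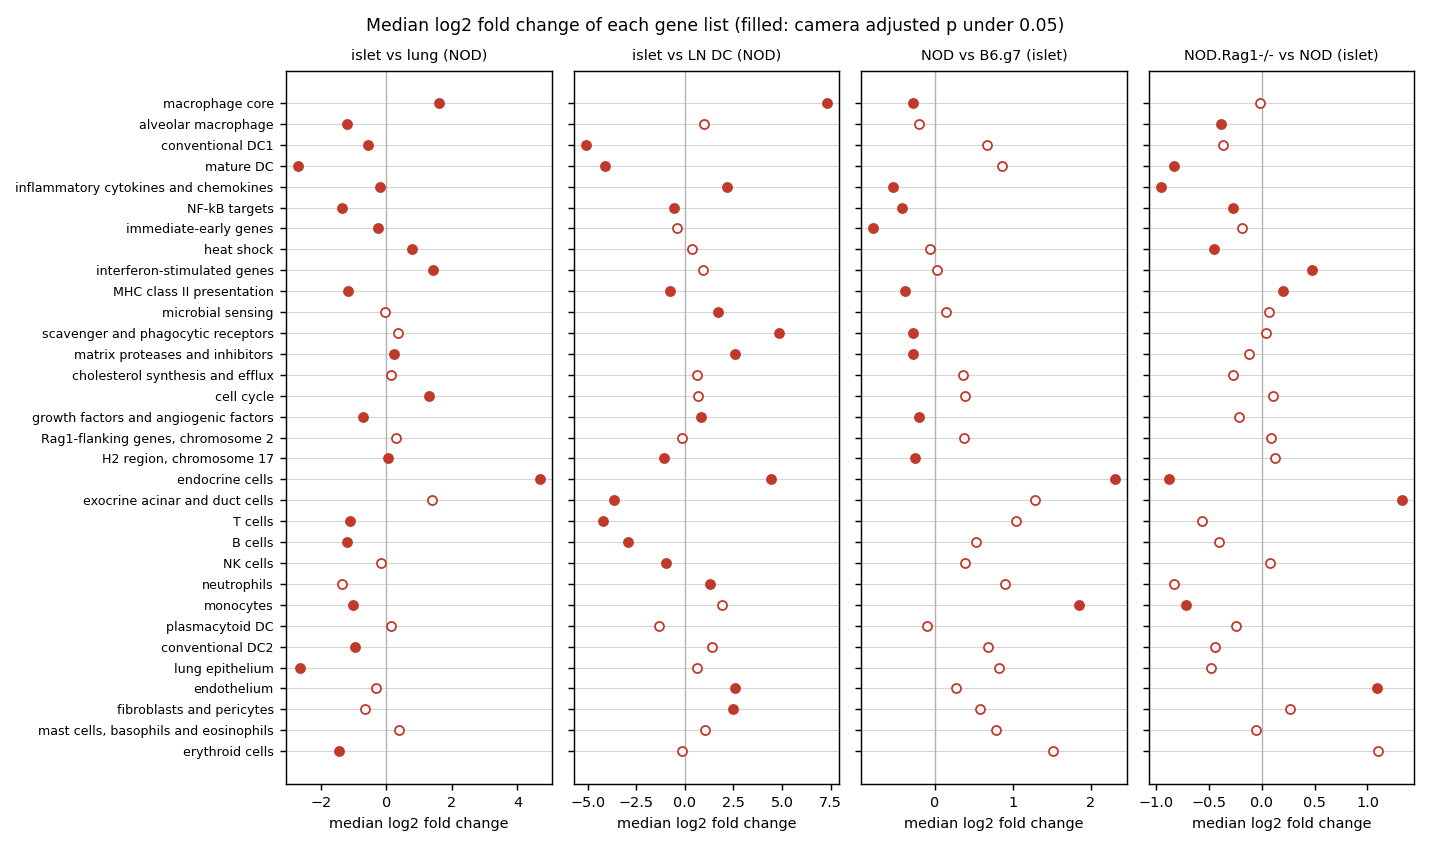
Median log2 fold change of the members of each list (horizontal axis) in the 4 comparisons, one panel each, with filled points for lists called by camera (adjusted p below 0.05). Against lung, mature dendritic cell genes lie at −2.69 and endocrine genes at 4.68, while against dendritic cells the macrophage core list lies at 7.33. Under quantile normalization the direction of the macrophage core list between NOD and B6.g7 reversed.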

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

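Each library was compared with the others of its group wherever a group held 4 or 5 libraries, for library measures and for every value named. In 35 of 248 such groups the highest or lowest library lay far from the rest by Dixon's criterion on normalized counts. Chance gives about 1 in 20, or about 12, if values are normally distributed and independent. Counts near the floor are skewed and genes of one library are not independent, so the excess over 12 is no test of a library. NOD islet library 4 accounts for 9 of them and NOD islet library 2 for 8. No explanation was tested for single libraries, and the genes named in the observations section were added to this comparison after their values were seen. The groups compared for each gene were narrowed to those with printed values after a first run. Over all 3 groups of each gene 57 of 385 lay apart, where chance gives about 19 under the same conditions.

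NOD islet library 4 lay low in several immune genes. Oasl2 was 441 (838.8 to 919 in the other 3), Cd80 50.6 (112 to 124), Tlr4 232 (317 to 332), Tlr3 276 (424 to 447), Fcgr1 2638 (4531 to 4699), H2-D1 3122 (5330 to 5472) and Flrt3 9.0 (19.4 to 21.3). Its Stag3 was high at 196 (87.9 to 92.3), and mitochondrial mRNA made up 1.65% of its reads (2.23% to 2.34%). The calls of NOD.Rag1-/- against NOD islet macrophages also depend on this library, with 68 genes called without it against 12 with it.

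NOD islet library 2 carried globin reads and a wider range of genes. Hbb-bs was 692 (0.7 to 1.6 in the other 3), Hbb-bt 169 (0 to 0.7) and Hba-a1 40.7 (0 to 2.0), so the globin values of the NOD islet group come from this library. Xcr1 was 208 (10.0 to 23.4), the dendritic cell gene Cacnb3 41.6 (3.2 to 9.3) and Oprd1 14.8 (0 to 0.7). Slco2b1 was 1278 (883.5 to 930.4), and 26314 genes were detected at equal depth (19356 to 20526). In NOD islet library 1, Oas1a was 155 (112 to 115).

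In lung macrophages, library 1 was high in Tlr4 (114.5, others 20.9 to 35.3), P2ry13 (50.5, others 1.4 to 8.0) and Rag1 (20.9, others 0). Library 2 was high in Oplah (22.2, others 0 to 1.2), and library 3 in Oasl2 (363, others 57.0 to 97.5) and Chrm3 (43.6, others 0 to 1.8). Library 4 was high in Rgs5 (49.7, others 0 to 1.4), Xcr1 (56.8, others 0) and Slco2b1 (152, others 2.5 to 17.7). In dendritic cells, library 1 was high in Adgre1 (54.2, others 0 to 14.1), library 2 in Chrm3 (80.3, others 0 to 3.6) and library 5 in Ms4a7 (26.4, others 0). Library 3 was high in Dab2 (24.6, others 0 to 3.6), Adamts1 (49.3, others 0 to 13.6), Oprd1 (2495.5, others 461 to 926) and Wdfy4 (45186, others 24252 to 29368). Library 4 was low in Tlr2 (88.1, others 193 to 216.5). Most of these are values near the floor, where a single library decides the group mean.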

How the results depend on the processing

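Alternatives with edgeR, quantile normalization, scaled to the total without rRNA and without the 2 libraries with the fewest genes were chosen after seeing the data. So was DESeq2 on recovered reads. The others were planned. Unless a cause is stated, the cause was not tested. The fit with a replicate block also held only the groups compared, and it left out libraries whose number the other group lacked. Its counts and values therefore cannot be put down to the block alone.

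The cell-type comparisons held best. Without any 1 library, 2195 to 3325 genes differed between islet and lung macrophages (3167 in the main test) and 3528 to 4546 between islet macrophages and dendritic cells (4570). The latter count moved beyond 1.5 times only with sample quality weights (7863). Genes higher in islet macrophages than in both others numbered 697, and 473 to 748 without 1 library, 1049 with quality weights, 454 by edgeR and 1409 scaled to the total without rRNA.

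The strain comparisons moved more. By edgeR and DESeq2 the islet fits also lacked NOD.Rag1-/- replicate 3. Without it limma gave 508 genes for NOD.Rag1-/- against B6.g7, 331 shared strain genes and 0 for NOD.Rag1-/- against NOD, so the lower counts of edgeR for these results are seen by limma as well and the higher ones of DESeq2 are not. NOD against B6.g7 gave 1320 genes, and 397 to 3156 without 1 library. The count was 814 with quality weights, 500 in one fit, 438 with only the groups compared, 494 with a replicate block (168 higher and 326 lower), 856 with a pseudocount of 10, 653 by edgeR, 2528 by DESeq2 and 848 under quantile normalization. NOD.Rag1-/- against B6.g7 gave 1421, and 508 to 3208 without 1 library, 639 in one fit, 220 with only the groups compared, 679 with a replicate block (304 higher and 375 lower) and 448 by edgeR. Shared strain genes numbered 778, and 313 to 2179 without 1 library, 282 in one fit, 130 with only the groups compared, 278 with a replicate block (91 higher and 187 lower), 512 with a pseudocount of 10, 304 by edgeR and 1403 by DESeq2.

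NOD.Rag1-/- against NOD gave 12 genes, and 0 to 68 without 1 library. It gave 1000 with quality weights, 30 in one fit, 1022 with only the groups compared, 1 with no robust prior, 52 by DESeq2 and 7 scaled to the total without rRNA. With a replicate block this comparison gave 2334, without B6.g7 and a NOD islet library, so the effect of the block alone was not tested. 0 genes were called with a stricter filter, with a pseudocount of 10 and by edgeR. The labels do not say whether replicate numbers pair the samples, and the values show no clear pairing. Fold deviations of libraries with the same number correlated at −0.05 to 0.16. The best match was the own number in 1 of 4, 0 of 4, 2 of 3, 0 of 3 and 2 of 3 libraries. So few libraries cannot exclude a pairing.

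Lists called with camera's preset correlation numbered 21, 19, 11 and 11 in the 4 comparisons. With an estimated correlation 3, 6, 0 and 0 were called, and with fry 5 and 5 in the strain and genotype comparisons, 3 and 3 of them among the lists called with the preset correlation. Without 1 library the numbers were 20 to 24, 17 to 22, 8 to 12 and 6 to 13. The direction of the macrophage core list between NOD and B6.g7 reversed under quantile normalization, to higher at an adjusted p of 0.68. Of the 62 called lists, all kept direction and call without a filter, with no robust prior and with a pseudocount of 0.5; 61 did under median-of-ratios rescaling, 58 by DESeq2, 50 by edgeR and 47 under quantile normalization.

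Of 379 values of named genes, 377 kept direction and call under median-of-ratios rescaling, 364 without a filter, 368 by DESeq2, 330 of 369 by edgeR, 338 under quantile normalization, 344 scaled to the total without rRNA and 327 with all 19 libraries in one fit. All reversed values belong to genes that the main test did not call. With a replicate block these were Xcr1 (0.0265) and Il1b (0.0946) for NOD against B6.g7 and Il1b (−0.0291) and Cd19 (−0.0763) for NOD.Rag1-/- against NOD. A pseudocount of 0.5 reversed Cd19 (−0.0149) in the latter. Quantile normalization reversed H2-Aa against dendritic cells (0.88), Adgre1 (0.0331) and Il1b (0.36) for NOD against B6.g7 and Il1b (−0.00475) for NOD.Rag1-/- against NOD. Scaling to the total without rRNA reversed H2-Aa against dendritic cells (0.16), Il1b for NOD against B6.g7 (0.20) and Cd19 for NOD.Rag1-/- against NOD (−0.0304).

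Leaving out 1 library gave ranges that cross 0 for these genes. For NOD.Rag1-/- against NOD they were −0.873 to 0.70 for Cd19, −2.09 to 0.16 for Xcr1 and −0.0291 to 0.48 for Il1b. For NOD against B6.g7 they were −1.39 to 0.92 for Xcr1 and −0.90 to 0.42 for Il1b, and for H2-Aa against dendritic cells −0.44 to 0.19. Depth limits genes near the floor: a gene listed at 0 allows an expected count of up to 3 per library.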

Other observations

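The tests of the excess of genes higher in NOD and of other splits of the samples were chosen after the result was seen, and the rule for judging the tests of the segments around Rag1 and H2 was made stricter after their values were seen. The other scalings in the test of the excess and the splits with only 2 groups in the fit were added later still. The other tests were set before their result was seen.

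Beside hormone genes, single genes were far higher in NOD islet macrophage libraries than in both other populations. After their values were seen, the 8 genes outside the endocrine list with the largest of the smaller of both fold changes were taken. What they share and RNA from other islet cells were not tested. Rgs5 led them at 561 ± 323 against 13.02 in lung macrophages and 6.38 in dendritic cells (smaller log2 fold change 6.85, adjusted p = 0.00076 and 0.00024). Oplah stood at 308 ± 90.9 against 5.85 and 0.54 and Klra2, a lectin-like receptor of the Ly49 family, at 310 ± 107 against 3.17 and 0.24 (adjusted p = 4.5e-05 and 1.1e-06). The matrix protease Adamts1 stood at 1660 ± 896 against 40.8 and 13.6, and the organic anion transporter Slco2b1 at 999.8 ± 186 against 43.6 and 7.32 (adjusted p = 0.0010 and 2.1e-05). AF529169 stood at 90.3 ± 22.2 against 0.3 and 0.48, and the ADP receptor P2ry13 at 642 ± 95.1 against 16.5 and 14.2 (adjusted p = 0.00032 and 0.00012).

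These genes were not confined to NOD. Rgs5 was 794.5 in NOD.Rag1-/- and 694 in B6.g7 islet macrophages, Slco2b1 1427 and 1792, P2ry13 823 and 382, and Klra2 489 and 980. AF529169 was 53.8 and 21.8, Adamts1 363 and 452, and Oplah 430.5 and 264. Chrm3, a muscarinic receptor gene also among the 8, was 332 ± 44.2 in NOD and 227 in NOD.Rag1-/- but 28.2 in B6.g7, against 11.4 in lung macrophages and 17.3 in dendritic cells. In each of these genes at least 1 value below the islet level rests on few reads, and no second set of islet macrophages was at hand.

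More genes were higher than lower in NOD than in B6.g7 islet macrophages, and fewer genes captured in the B6.g7 libraries may account for this excess, which would then be missing among genes of high counts. Of 598 called genes with a mean of at least 100, 208 (34.8%, exact 95% interval 31.0% to 38.8%) were higher in NOD, against 91.8% of 722 called genes with a lower mean. The share among genes of high counts was 35.6% under median-of-ratios rescaling. It turned to 61.5% under quantile normalization and 79.3% scaled to the total without rRNA. Those scalings also moved the median log2 fold change of genes with a mean of at least 100, from −0.02 to 0.13 and 0.30. Of 871 genes called higher in NOD, 440 (50.5%) had 2 or 3 B6.g7 libraries at 0. The share depends on the scaling, so the test does not decide. Capture and strain go together in these samples, and a strain difference stays open.

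As lists by camera, interferon-stimulated genes were higher and cytokine genes lower in NOD.Rag1-/- than in NOD islet macrophages. With an estimated correlation neither was called (adjusted p = 0.096 and 0.092), and by limma 0 of 35 and 0 of 30 members were called over all genes. Fold changes in this comparison rose with transcript length (Spearman rho 0.25 across 11673 genes, which are not independent replicates), so each library's trend with length and GC content was removed, leaving a rho of 0.015. The median of the interferon list was 0.48 before and 0.51 (0.505) after, and that of the cytokine list −0.95 before and −0.77 after, so length and GC content did not account for the whole of either, although the cytokine members vary widely (SD 1.30). After the correction 0 genes were called by limma (smallest adjusted p 0.054, 1496 at an unadjusted p below 0.05), against 12 before. The interferon median was 0.54, 0.48 and 0.47 without NOD.Rag1-/- libraries 1, 2 and 3, so it does not rest on 1 of them; an effect of lymphocytes and differences in how the 2 genotypes were sampled both stay open, and no batch labels are given.

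Hormone RNA in islet macrophage libraries may come from endocrine cells, as RNA or debris carried into the sorted material. Within groups 22 endocrine genes varied together (mean pairwise r 0.28, at percentile 99.99 of 10000 random lists of like expression, whose median was −0.0059 and highest 0.28). Carry-over and uptake of endocrine material by macrophages both predict this, and the test cannot separate them. Expression in the macrophages themselves was not tested. The sort took CD45+ cells, which should remove intact endocrine cells.

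Of genes within 10 Mb of Rag1 (chromosome 2, 91638282 to 111649501), 6 of 152 (3.95%) were called between NOD.Rag1-/- and NOD with only these groups in the fit, against 989 of 23663 (4.18%) elsewhere (Fisher's exact test, one-sided p = 0.61). A segment from the donor strain of the targeted allele would raise this share, but 6 genes are too few to decide. Between H2-K1 and H2-M3 (chromosome 17, 33996017 to 37274484) 6 of 187 genes (3.21%) were called between NOD and B6.g7, against 1257 of 24631 (5.10%) elsewhere (Fisher's exact test, one-sided p = 0.16), which leaves open whether the shared H2 region lowers the share.

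Other splits of the samples were tested for each comparison. For islet against lung macrophages 1 of 35 splits, the real one, gave as many genes (3167, highest other 5). For NOD against B6.g7 1 of 35 did (1320, highest other 16). Both real splits gave far more genes than any other, but 1 of 35 is the smallest share these splits can give. For islet macrophages against dendritic cells 1 of 100 splits drawn from 126 did (4570, highest other 2339), again the smallest share possible. The highest other split set dendritic cell libraries 2 to 5 against the islet libraries with dendritic cell library 1, close to the mirror of the real one. These tests were chosen after the results were seen, so the splits alone do not exclude chance. For NOD.Rag1-/- against NOD with all 3 islet groups in the fit 2 of 35 splits gave as many (12, highest other 25, with NOD islet libraries 1 to 3 against the rest). That split only moves NOD islet library 4, so it keeps most of the genotype contrast and cannot decide for these 12 genes. With only these groups in the fit 1 of 35 splits, the real one, did (1022, highest other 858, by the same split). That fit was tested later and 1 of 35 is the smallest share it can give, so chance is not excluded in either fit. For NOD.Rag1-/- against B6.g7 the 10 splits, of which 1 gave as many, are too few for a share under 0.05 (1421, highest other 0).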
